A study of Arabidopsis thaliana with 3 samples.

How the data were processed

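SOB3 (SUPPRESSOR OF PHYB-4 3) is an AT-hook protein of Arabidopsis thaliana that represses seedling growth. Chromatin was taken from whole Col-0 plants of 14 days that carry a SOB3-GFP fusion under the SOB3 promoter in the sob3-4 background, harvested 4 h after lights-on (ZT4) at 22 °C in days of 16 h light and 8 h dark, per the labels. The fusion was precipitated with an anti-GFP antibody in 2 ChIP replicates, and 1 input library had no antibody. Each ChIP replicate had a peak list; no file of the input library was used here. The labels do not say whether the replicates came from separate plantings, so differences between them measure only the spread between these samples, which may be technical.

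Reads were converted with bcl2fastq, aligned with Bowtie 0.12.9 to TAIR10 and searched for peaks with MACS2, per the submitters' processing notes; the MACS2 version, its control and its threshold are not given in the sources used here. Peak names in the files number each replicate's peaks separately, so peaks were called per replicate and not on pooled reads. The authors' fold enrichment is a linear ratio of the pileup at the summit to the control value, as MACS2 writes it. The authors' −log10 p and −log10 q columns come from the same caller. The lowest −log10 q was 1.33 in replicate 1 and 1.30 in replicate 2, close to the 1.30 of a q-value of 0.05. The authors' score column held the whole part of 10 times −log10 q in 100% of peaks and added nothing. The other deposited columns give the position, name and summit of each peak. Fold values are the authors' own and served to describe and rank peaks within a list and to set the replicates side by side.

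Peaks of the 2 lists were called shared when they overlapped by at least 1 bp. Overlapping peaks were joined into shared regions, with the summit of the replicate 1 peak of highest fold and, per replicate, the fold of its highest peak. The overlap was compared with 1000 random placements of the replicate 2 peaks on their chromosomes (1-sided permutation p). Runs of N were not excluded from placement, because no genome sequence was used here. Spearman and Pearson correlations of fold across shared regions (Pearson on log2 fold) had permutation tests with 100000 resamples.

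Genes came from an NCBI RefSeq table of assembly TAIR10.1, which gives each gene's span but no strand, exons or sequence; 27432 protein-coding genes on chromosomes 1 to 5 were used. Its nuclear chromosomes are taken to have the coordinates of TAIR10, none of its coordinates are printed, and the places of summits relative to genes rest on that. Summits were sorted into those inside a protein-coding gene span, inside another annotated gene, within 1 kb of a protein-coding gene, or farther away, and compared with 1000 rotations of all summits along each chromosome (2-sided, Benjamini-Hochberg over the classes). The planned classes by exon, intron and UTR, distance to the transcription start, A+T content and motif counts needed strand or sequence and were not run. A gene was called bound when a summit lay in its span or within 1000 bp to either side; the planned window used the upstream side and the gene alone. Bound, here and below, means only that a peak lies there. A summit can count for more than 1 gene, so neighbouring genes, also of the same list, can be bound through 1 region.

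Before the data were examined, 18 gene lists were fixed by locus and 9 families by symbol. Of 281 distinct loci in the lists, 280 were in the table, and the gene of SOB3 itself is not reported here. Each list was tested against all other protein-coding genes with a 2-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 27 lists, and against 10000 random lists matched on deciles of gene length and of the gaps to neighbouring genes. The gaps on both sides were summed, whereas the planned matching used the upstream gap alone, which needs strand. Genes are named by a rule fixed at the same time: PIF4, PIF5, PIF7, YUC8, YUC9, IAA19, IAA29, HB-2, PHYB, AHL27 and the SAUR19 subfamily always, the genes nearest to the 10 shared regions with the highest lower fold of the 2 replicates, and up to 4 bound members per locus list with the highest lower fold. The remaining members are given as counts, and others named in the text were chosen after their values were seen.

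Peak lists carry no read totals. The signal was therefore recovered from the fold and p columns by solving the MACS2 formulas for the summit pileup and the control value. Summit pileups were whole multiples (within 0.02) of 0.720 in replicate 1 for 99.98% of peaks and of 0.821 in replicate 2 for 100% of peaks. Most peaks had more than 1 solution (83.5% in replicate 1 and 90.0% in replicate 2, at most 4), and the solution nearest to a whole multiple was taken. Of the 1642 and 477 peaks with 1 solution, on which the step was fitted, 100% were whole. With 100 other steps the same choice among solutions gave a mean of 8.04% and 8.65% whole over all peaks (at most 15.8% and 18.7%). These steps are what 1 fragment was worth after scaling to the control, so replicate 1 held 1.39 and replicate 2 held 1.22 times as many fragments as the control, a depth ratio of 1.14. Summits rested on 42 to 259 fragments in replicate 1 and 38 to 163 in replicate 2. Among 1023 peak pairs with summits within 50 bp and whole control values in both lists, the control values differed by at most 1 in 64.1%, against 17.9% for independent Poisson counts, as would arise from 1 control library behind both lists. The kept values all lay above the lowest control value of their list, and the simulated counts were not held to that. The 17.9% can therefore be too low a reference. Absolute depth is unknown. Intervals for shares are Wilson or exact (Clopper-Pearson) 95% intervals and cover counting error only.

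The alternatives were a −log10 q of at least 10, the top 1000 peaks per list, a reciprocal overlap of 50%, summits within 100 bp, each replicate's list alone, the replicate 2 summit, replicate 2 peaks moved by 5 to 50 kb, flanks of 2 kb, the nearest gene within 3 kb, and matched lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The permutation tests, the gene list tests and the recovery of signal were tested on simulated data. With 1000 planted overlapping peaks among 2000 random ones, 1129 of 9980 replicate 1 peaks were found overlapped, and random peaks alone gave 0.928 times the placement mean. Among 27432 genes, planted lists of 20 genes with 50% bound were called in 85.5% of 200 simulations by Fisher's test and 82% by matched lists, and other lists in 0.2% and 0.075%. Smaller planted lists and lower planted shares were not simulated. The simulated lists were drawn at random from all genes. The 0.2% for Fisher's test thus does not cover lists of genes with unusual length or spacing. A planted correlation of 0.1 over 3823 regions was called in 100% of 200 simulations, and unrelated folds in 5% (Pearson) and 6.5% (Spearman). With 10% of 3000 random summits planted beside genes, rotation called the class within 1 kb, the distance to gene edges and the number of bound genes in 100% of 20 simulations, and with none planted in 0%, 6% and 5% of 100. A planted difference of 5 percentage points within deciles of 9980 peaks was called in 99.5% of 200 simulations (mean recovered 5.01), and no difference in 6%. In these the shares depended on the decile itself, without error in peak strength. A planted step of 0.8 was recovered as 0.8 over 2991 simulated peaks.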

Results

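The binding of SOB3-GFP to chromatin was mapped by ChIP-seq in whole juvenile Arabidopsis plants, to learn where this AT-hook repressor of growth sits in the genome and whether it occupies genes that the phytochrome-interacting factors (PIFs) are known to regulate. The series held 2 ChIP replicates and 1 input library of the same line. The replicate 1 list held 9980 peaks with a median width of 349 bp and a median fold enrichment of 2.58 (range 1.51 to 10.5). The replicate 2 list held 4788 peaks with a median width of 295 bp and a median fold of 2.47 (range 1.60 to 6.60). All peaks lay on chromosomes 1 to 5. The depth recovered from the peak columns was 1.14 times higher in replicate 1 than in replicate 2.

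The first comparison asked which regions were held in both replicates. The strongest shared region by the lower of both folds lay on chromosome 3 (11550433 to 11551036, TAIR10) at AT3G29720, with a fold of 7.46 in replicate 1 and 6.38 in replicate 2. It was followed by chromosome 1, 24263856 to 24264560 (6.19 and 6.60), nearest to CBSX6 (AT1G65320) but more than 1 kb from it, and by chromosome 4, 6027020 to 6027655 (7.44 and 5.71), beside AT4G09520. The region on chromosome 2 at 14522259 to 14522863 (6.37 and 5.47) lay in LHB1B2 (AT2G34420), a chlorophyll a/b-binding protein gene, and in its overlapping neighbour RWA3 (AT2G34410). Of the 10 strongest regions, 6 lay in or within 1 kb of a protein-coding gene, among them HAT14 (AT5G06710, 4.92 and 5.17), a homeodomain leucine-zipper gene, FH6 (AT5G67470, 4.98 and 4.97) and AT1G77790 (8.06 and 4.86). The other 4 were farther from any protein-coding gene, with CBSX6, AT5G30495, CYP96A8 and AT2G12646 as the nearest.

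In all, 3842 replicate 1 peaks (38.5%) and 3922 replicate 2 peaks (81.9%) overlapped a peak of the other list and formed 3823 shared regions with a median width of 442 bp. Random placement gave 296 ± 17.1 overlapped replicate 1 peaks (SD over 1000 placements), so the observed number was 13.0 times higher (1-sided permutation p = 0.001, the smallest these placements can give). The summits of the 2 replicates lay a median of 39 bp apart. Fold enrichment correlated across the shared regions with a Spearman rho of 0.37 and a Pearson r of 0.40 on the log2 scale (permutation p = 1e-05 for each, the smallest possible), across regions, which are not independent replicates. Fold was higher in replicate 1 in 67.4% of the regions, with medians of 2.89 and 2.53. Part of the overlap and of the fold correlation can come from the control, since the control values behind both lists were mostly close where compared. Neither test allows for this.

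Overlap was more frequent among stronger peaks in both lists. Among replicate 1 peaks, 78.4% of the strongest decile by −log10 q (Wilson 95% interval 75.7% to 80.8%) and 17.6% of the weakest decile (15.4% to 20.1%) overlapped a replicate 2 peak. In replicate 2 the shares were 98.5% (97.0% to 99.3%) and 70.4% (66.1% to 74.3%). This left 6138 replicate 1 peaks with a median fold of 2.44 and 866 replicate 2 peaks with a median fold of 2.30 without a partner.

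**Figure D1:**
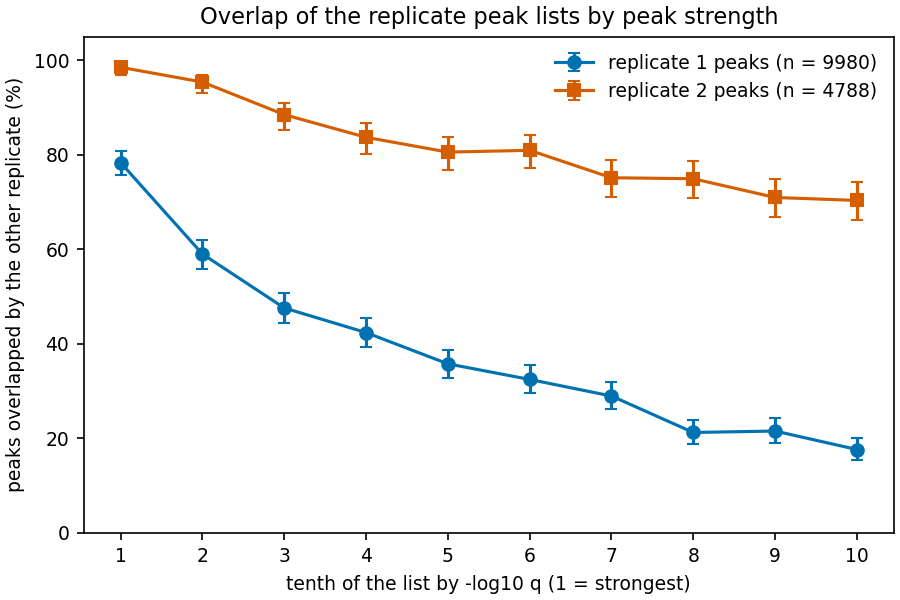
Share of each replicate's peaks (%, vertical axis) that overlap a peak of the other replicate by at least 1 bp, in deciles of the list by −log10 q from strongest to weakest; bars are Wilson 95% intervals. The share falls from 78.4% to 17.6% in replicate 1 and from 98.5% to 70.4% in replicate 2.

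**Figure D2:**
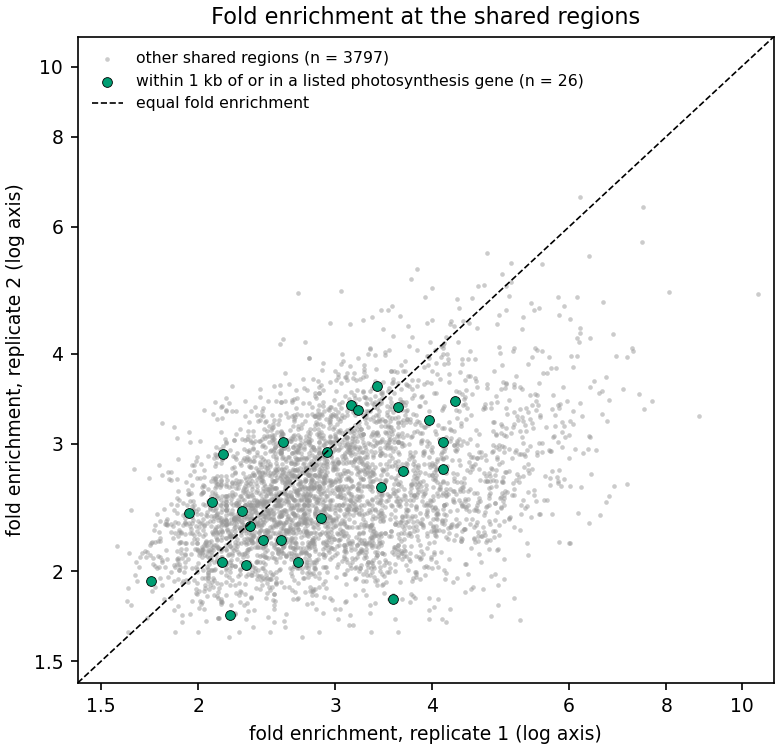
MACS2 fold enrichment of each shared region in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with the 26 regions at listed photosynthesis genes in green and 3797 others in grey. In 67.4% of all regions the fold is higher in replicate 1, to the right of the dashed line of equal fold.

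SOB3-GFP regions lay next to genes far more often than in them. Of the 3823 summits, 1922 (50.3%, exact 95% interval 48.7% to 51.9%) were within 1 kb outside a protein-coding gene, against a mean of 19.0% when the same summits were rotated along the chromosomes. Only 17.2% (16.0% to 18.4%) lay inside a protein-coding gene span, against 54.1%, and 1.54% inside another annotated gene, against 9.99%. A further 31.0% lay farther than 1 kb from any protein-coding gene, against 16.9%. Each difference had an adjusted permutation p of 0.002, the smallest 1000 rotations can give. Summits outside genes lay a median of 645 bp from the nearest gene edge, against 1265 bp for rotated summits (permutation p = 0.002), and the bin with the most summits was the first 100 bp outside the edge, with 9.68% of summits against 3.55%. Which edge is the start of the gene was not used here, so upstream and downstream sides are pooled, and rotation also moves summits into stretches where reads align poorly. Replicate 1 peaks without a partner gave nearly the same share within 1 kb of a gene (49.0%, against 19.1% after rotation). The series held no precipitation from plants without the fusion. Whether signal recovered without SOB3-GFP lies at the same places was therefore not tested.

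**Figure D3:**
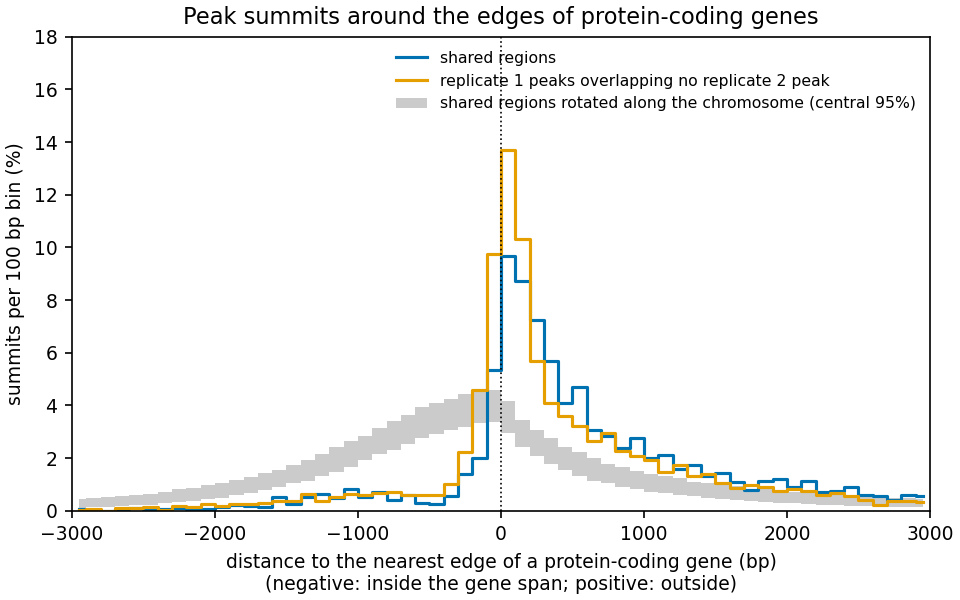
Share of summits (%) per 100 bp bin by distance to the nearest edge of a protein-coding gene (bp, negative inside the span), for shared regions (blue), replicate 1 peaks with no replicate 2 partner (orange) and the central 95% of 1000 rotations of the shared summits (grey). Shared summits peak in the first 100 bp outside the edge, at 9.68% against 3.55% after rotation.

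The next question was whether the genes of PIF transcription factors and their growth targets carry SOB3-GFP. PIF4 (AT2G43010), the factor that drives petiole and stem elongation in warmth and shade, had a shared region at chromosome 2, 17889200 to 17889889, with a fold of 2.72 in replicate 1 and 2.44 in replicate 2. PIF5 (AT3G59060, 2.67 and 2.92), PIF7 (AT5G61270, 2.92 and 2.38) and PIF8 (AT4G00050, 2.996 and 2.77) were also bound in both replicates, each with the summit outside the gene span. In all, 6 of 16 PIF and phytochrome genes were bound (37.5%, against 11.5% of other genes by Fisher's exact test, adjusted p = 0.0356). PHYB (AT2G18790), the red-light receptor, had a peak in replicate 1 only, with a fold of 2.82. The call was lost against random lists matched on gene length and spacing (mean 2.51 bound, adjusted permutation p = 0.37), without replicate 1 (adjusted exact p = 0.0835), with summits within 100 bp (0.0781), and at −log10 q of at least 10 or with the top 1000 peaks (1 in each, with none of the 16 genes bound). It was also lost with a reciprocal overlap of 50%, where PIF4 and PIF7 had no shared region and the odds ratio went from 4.78 to 1.62 (adjusted exact p = 0.96).

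Among the listed growth targets of PIFs, IAA29 (AT4G32280), an early auxin response gene, had a region at chromosome 4, 15585066 to 15585443, with folds of 3.74 and 4.103. The expansin gene EXPA8 (AT2G40610, 2.80 and 2.83), LNG2 (AT3G02170, 2.97 and 2.67) and the auxin synthesis gene YUC2 (AT4G13260, 3.42 and 2.64) were bound in both replicates as well. In contrast, YUC8 (AT4G28720), YUC9 (AT1G04180), IAA19 (AT3G15540) and HB-2 (AT4G16780) had peaks in replicate 1 only, with folds of 2.33, 1.87, 2.62 and 2.65. Of 28 PIF growth targets, 8 were bound in both replicates (28.6%; adjusted p = 0.0508, Fisher's exact test), which did not pass. The replicate 1 list alone held 20 of them (adjusted exact p = 4.77e-05, and 0.0036 against matched lists) and the replicate 2 list 8 (adjusted exact p = 0.179).

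Auxin genes were tested as separate lists, each against other genes and not against each other. Of the auxin transport genes 6 of 15 were bound (adjusted p = 0.0308, Fisher's exact test, 0.0736 without replicate 1, and 0.459 against matched lists), including the efflux carriers PIN3 (AT1G70940, 4.54 and 3.93), PIN7 (AT1G23080, 4.79 and 2.67) and PIN8 (AT5G15100, 4.25 and 2.74) and the influx carrier AUX1 (AT2G38120, 3.50 and 3.32). Of 29 Aux/IAA repressor genes 5 were bound (adjusted exact p = 0.504), with IAA16 (AT3G04730, 4.58 and 4.96), IAA8 (AT2G22670, 5.48 and 3.65) and IAA2 (AT3G23030, 4.84 and 2.86) besides IAA29. Of 14 auxin biosynthesis genes only YUC2 was bound in both replicates. In the SAUR19 subfamily of small auxin-induced genes, SAUR20 (AT5G18020, 4.71 and 2.67) and SAUR21 (AT5G18030, 5.82 and 2.197) were bound in both lists and SAUR24 (AT5G18080) in replicate 1 only (2.33), while SAUR19, SAUR22 and SAUR23 had no peak in either list. These near-identical neighbours can share reads, so which member carries the signal is uncertain.

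The photosynthesis list had the highest share of bound genes of the 27 lists. Of 18 genes for light-harvesting proteins and the small subunit of Rubisco, 17 were bound in both replicates (94.4%, exact 95% interval 72.7% to 99.9%, against 11.4% of other genes by Fisher's exact test, adjusted p = 4.43e-14). Random lists matched on gene length and spacing held a mean of 2.26 bound genes (adjusted permutation p = 0.0054). Its strongest members were LHCB4.1 (AT5G01530, 4.27 and 3.44), LHCB3 (AT5G54270, 3.40 and 3.61), LHCB2.2 (AT2G05070, 3.62 and 3.38) and RBCS3B (AT5G38410, 3.97 and 3.24). LHB1B2 (AT2G34420), at the stronger region named above (6.37 and 5.47), was not on the list. Copies of LHCB1, LHCB2 and RBCS are near-identical, so single members of these are uncertain. Under the top 1000 peaks of each list the call was lost (adjusted exact p = 0.12).

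Gibberellin genes were bound more often than other genes, with 8 of 20 (adjusted p = 0.0143, Fisher's exact test, and 0.278 against matched lists). They included the receptor gene GID1B (AT3G63010, 4.21 and 3.03), the catabolic genes GA2OX3 (AT2G34555, 3.23 and 3.69) and GA2OX4 (AT1G47990, 2.34 and 2.40) and the biosynthetic GA3OX2 (AT1G80340, 2.82 and 2.77). Of the 10 listed TCP genes, which shape leaf growth, 5 were bound (adjusted p = 0.0275, Fisher's exact test, 0.06 without replicate 1, 0.0605 with flanks of 2 kb, 0.0754 with a reciprocal overlap of 50%, and 0.286 against matched lists), with TCP5 (AT5G60970, 3.84 and 2.81), TCP3 (AT1G53230, 3.86 and 2.65) and TCP2 (AT4G18390, 2.58 and 2.68) among them. Of 17 genes whose symbol begins with TCP, 7 were bound (41.2%). That share did not pass when adjusted over 362 such symbol groups (Fisher's exact test, adjusted p = 0.162), a test chosen after the results were seen. Brassinosteroid genes did not pass (5 of 18, adjusted p = 0.161, Fisher's exact test), though BIN2 (AT4G18710, 3.95 and 3.19), the receptor BRI1 (AT4G39400, 3.44 and 2.92) and the biosynthetic CPD (AT5G05690, 3.68 and 2.75) were bound.

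The other locus lists did not pass Fisher's exact test. Cytokinin genes had 4 of 17 bound (adjusted exact p = 0.286), with CKX7 (AT5G21482), a cytokinin-degrading oxidase, at 5.88 and 3.11. Of the cell wall loosening genes 5 of 17 were bound (adjusted exact p = 0.146), with XTH24 (AT4G30270) at 3.10 and 2.86. Of 14 clock genes 3 were bound (adjusted exact p = 0.323), namely RVE1 (AT5G17300, 3.58 and 2.32), PRR9 (AT2G46790, 3.73 and 2.25) and GI (AT1G22770, 3.48 and 2.07). Growth-related bHLH genes had 3 of 13 (adjusted exact p = 0.323), BEE1, BEE2 and PRE2, and flowering genes 3 of 11 (adjusted exact p = 0.286), SVP, AP1 and SOC1. Of 28 genes of SOB3's own AHL family 6 were bound (adjusted exact p = 0.286), led by AHL2 (AT4G22770, 5.22 and 4.34), and AHL27 (AT1G20900), a close relative of SOB3, had no peak in either list. The SAUR19 subfamily had an adjusted exact p of 0.301 and auxin biosynthesis one of 1. Among the comparison lists, housekeeping genes had 2 of 12 bound, ACT7 and UBQ10 (adjusted exact p = 0.785), and seed storage genes 1 of 12, CRA1 (adjusted exact p = 1).

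The 9 families taken by symbol did not pass either. Bound in both replicates were 13 of 80 SAUR, 9 of 71 WRKY, 5 of 25 ERF, 13 of 100 NAC, 16 of 125 MYB, 5 of 25 ARF, 5 of 29 expansin, 7 of 33 XTH and 5 of 49 ribosomal protein genes, with adjusted p from 0.285 to 1 in Fisher's exact test. Over all protein-coding genes, 3152 of 27432 (11.5%) were bound, against 3383 ± 54.1 (SD) under rotation (permutation p = 0.002). This direction turned without replicate 2, since the replicate 1 list alone bound 7882 genes against 7385 ± 152 (permutation p = 0.002), while the replicate 2 list alone bound 3760 against 4061 ± 64.2 (permutation p = 0.002). With Fisher's exact test 5 of the 27 lists passed, and with matched random lists 1, photosynthesis. At −log10 q of at least 10 only photosynthesis passed Fisher's exact test, and with the top 1000 peaks 0 lists did (3 had an unadjusted p under 0.05), with no listed TCP gene bound in either.

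**Figure D4:**
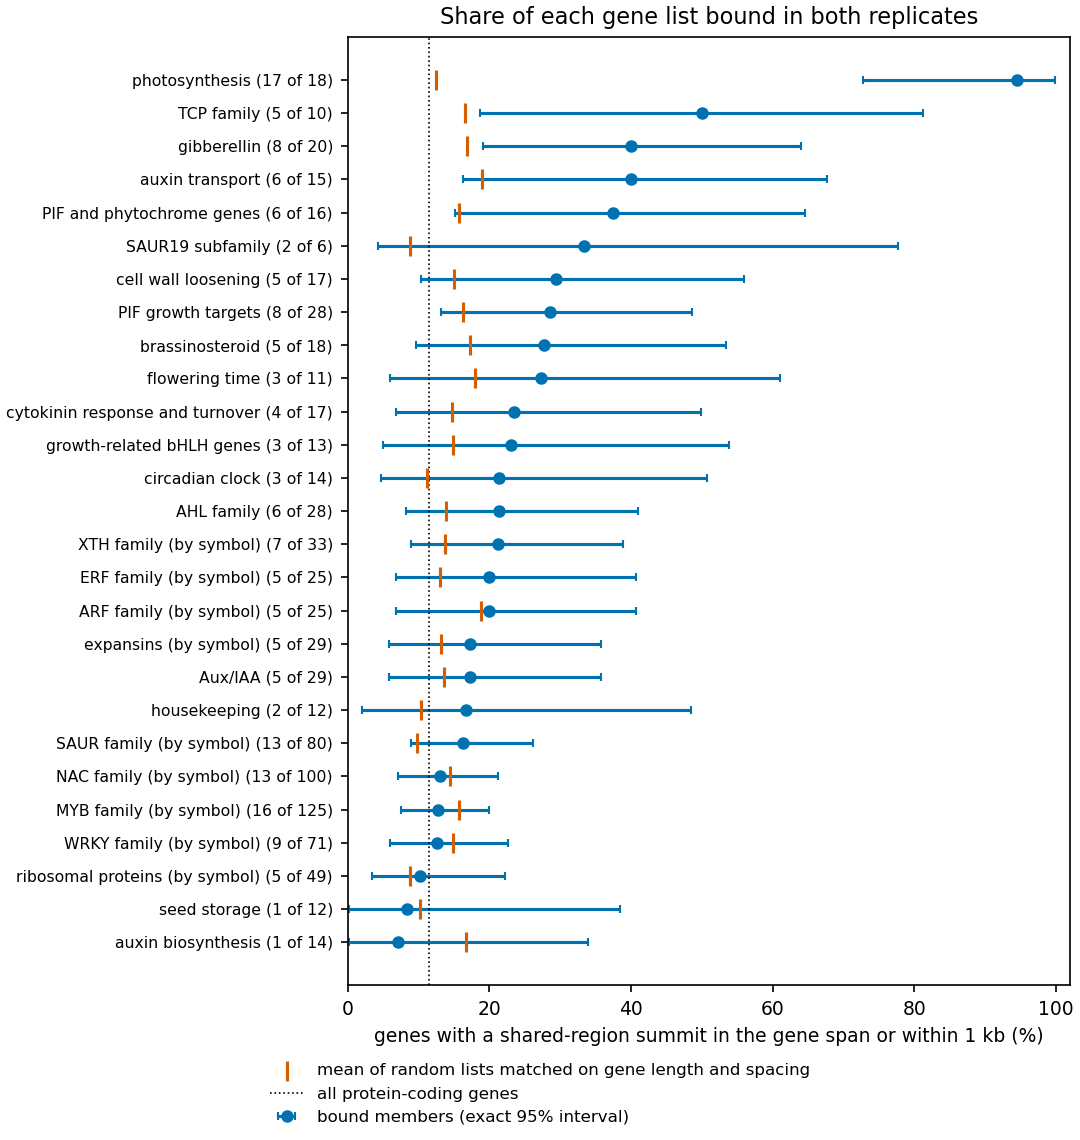
Share of each list's genes (%, horizontal axis) with a shared-region summit in the gene span or within 1 kb; points carry exact 95% intervals, orange marks show the mean of matched random lists, and the dotted line marks all protein-coding genes (11.5%). Photosynthesis lies at 94.4%, and the other lists lie between 7.14% and 50%.

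The single lists gave different sets of genes. The replicate 1 list bound 7882 genes and the replicate 2 list 3760, with 3210 in both. In the replicate 1 list 16 of 27 gene lists passed Fisher's exact test and 9 passed against matched lists, including PIF growth targets (20 of 28), gibberellin (15 of 20, adjusted permutation p = 0.0108 against matched lists), brassinosteroid (13 of 18, 0.0216), ERF genes (16 of 25, 0.0081) and housekeeping genes (9 of 12, 0.0135). In the replicate 2 list 2 passed Fisher's exact test, photosynthesis and gibberellin, and 1 passed against matched lists, photosynthesis. Lists of such different length differ in what they can pass, and the difference between them was not tested.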

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

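Of the tests in this part, the one within deciles of −log10 q was fixed before its result was seen; the gene list tests on peaks without a partner, the test on housekeeping and ribosomal protein genes together, and those on the number of peaks, were chosen after. Flagged are peaks that stayed outside the shared regions: 6138 replicate 1 peaks and 866 replicate 2 peaks, signals in data the main comparisons set aside. A gene touched by a peak without a partner can also have a shared region, so these are not all separate genes. Of the 28 PIF growth targets, the replicate 1 list held 20, while 8 had a shared region and 18 a replicate 1 peak without a partner. In the replicate 1 peaks without a partner 12 of 27 gene lists passed Fisher's exact test and 8 passed against matched lists, so the signal was not particular to 1 list. The 8 were PIF growth targets (18 of 28 genes touched, 64.3%, against 19.95% of other genes; adjusted p = 1.12e-05 in Fisher's exact test, 0.0018 against matched lists), brassinosteroid (12 of 18, 0.0018 against matched lists), SAUR (25 of 80, 0.0018), ERF (13 of 25, 0.00216), housekeeping (9 of 12, 0.00216), growth-related bHLH (8 of 13, 0.0207), cytokinin (10 of 17, 0.0208) and Aux/IAA genes (13 of 29, 0.0277).

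Replicate 1 gave 2.08 times as many peaks as replicate 2. Its recovered depth was 1.14 times higher, which argues against depth as the whole cause, since the recovered values show both libraries scaled to the control. The lowest control value, which grows with the length to which reads were extended, was 1.02 times higher, below the 1.15 median ratio of summit signal, which argues against longer extension. After scaling, summit signal was higher in replicate 1 at 73.4% of 3941 overlapping peak pairs (median ratio 1.15, quartiles 0.991 and 1.44). Stronger enrichment in replicate 1 would give this. It largely restates the higher fold in replicate 1, since the control values of both lists were mostly close where compared, and is not separate evidence. Whether stronger enrichment would come from the precipitation or the plants stays open. No biological explanation was tested because the design has 1 group.

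Replicate 1 peaks without a partner lay nearer to gene edges: 42.8% had their summit within 250 bp of an edge, against 30.4% of replicate 1 peaks with a partner. If they were merely weaker sites of the same kind, the shares were predicted to match at equal replicate 1 −log10 q. Within deciles of −log10 q they differed by 14.4 percentage points (permutation p = 0.0005, the smallest 2000 permutations can give), with the unpartnered share higher in 9 of 10 deciles. That −log10 q measures strength in 1 replicate with error, and at an equal value the peaks with a partner can be the stronger sites. The deciles thus cannot decide whether the unpartnered peaks are weaker sites of the same kind. Background at the edges of active genes stays open: 15 of 61 housekeeping and ribosomal protein genes had such a peak (24.6%, against 19.99% of other genes; Fisher's exact p = 0.341), but taken separately, 9 of 12 housekeeping genes (adjusted p = 0.000557) and 6 of 49 ribosomal protein genes (adjusted p = 0.26) did. The genes of the 8 lists in this set thus cannot be told apart as sites of SOB3 or background; no biological explanation was tested.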

How the results depend on the processing

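The direction and the side of the threshold held under the alternatives run for the replicate overlap (11.9 to 39.2 times random placement), the fold correlation (rho 0.25 to 0.43), the share of summits within the flank of a gene (49.4% to 64.3%, the highest with a flank of 2 kb) and the distance to gene edges. Counts moved. With −log10 q of at least 10 there were 605 shared regions, 507 bound genes and 1 gene list past the threshold; with the top 1000 peaks of each list 314, 270 and 0 (3 lists had an unadjusted p under 0.05). Fewer peaks enter both settings. Gene lists past the threshold numbered 3 with a reciprocal overlap of 50%, 11 with the nearest gene within 3 kb and 1 with matched random lists; the cause was not tested. In 2 settings chosen after seeing the data, flanks of 1 kb alone gave 2 lists, and summits inside the gene span alone gave 632 bound genes, a narrower window, and 6 lists. Leaving out each replicate gave 3760 to 7882 bound genes and 2 to 16 lists. The other location classes kept their call and direction in all 24 comparisons. For the 27 gene lists, 324 comparisons over 12 settings gave 226 with call and direction kept, 19 calls lost, 19 gained by 13 lists, and 60 in which the share turned to the other side of that of other genes or matched lists, for 20 lists. Of the gains 11 came without replicate 2 and 6 with the nearest gene, and none of the turned shares passed the threshold. Turned from a call, with no gene bound, were PIF and phytochrome genes (−1.85 percentage points from other genes at −log10 q of at least 10, −0.985 with the top 1000 peaks, −2.31 inside the gene span alone) and TCP genes (−1.85 and −0.985 in the first 2 of these). PIF growth targets, not called before, also turned with the top 1000 peaks (−0.985). The number of bound genes lay below that of rotated summits with both replicates and without replicate 1, and above it without replicate 2 (7882 against a mean of 7385, permutation p = 0.002). Among 66 genes named from the lists, 41 of the 56 bound were lost at −log10 q of at least 10, 46 with the top 1000 peaks and 16 with a reciprocal overlap of 50%. The narrower and wider windows for sequence content, the promoter-only window and the A+T, motif and transcription-start results were not run, because strand and sequence were not used here. No paired analysis was possible because the design has 1 ChIP group and 1 input library without a replicate number. Overlap and correlation need both replicates and have no value without one. Depth per list is known only relative to the control, and a site without a replicate 2 peak is not shown to be absent there.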

Other observations

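Of the tests in this part, the matched lists for the photosynthesis list were planned, though with the upstream gap in place of the gaps on both sides. So was Fisher's exact test of the housekeeping and the ribosomal protein list, each taken separately, in the replicate 1 list. The others were chosen after the results were seen. Beyond the listed genes, SOB3-GFP regions lay at other genes of the photosynthetic apparatus. Of 25 nuclear genes for photosystem subunits outside the list, 16 were bound in both replicates (64.0%, against 11.4% of other genes; Fisher's exact p = 6.55e-10) and 22 in the replicate 1 list. They included PSAL (AT4G12800, fold 4.51 in replicate 1 and 2.88 in replicate 2), PSBX (AT2G06520, 3.14 and 2.97), PSBW (AT2G30570, 3.10 and 2.98) and PSBQ-2 (AT4G05180, 2.95 and 3.37), while PSBQA, PSBP-2 and PSAE-2 had no peak in either list. Among 362 symbol stems with at least 6 genes, 3 passed Fisher's exact test after adjustment: LHCB (8 of 9, adjusted p = 8.83e-05), CYP (46 of 229, 0.0275), and HAT, homeodomain leucine-zipper genes (5 of 7, 0.0414). Genes were grouped by symbol alone, so the CYP stem can hold genes of more than 1 family. The LHCB stem includes genes of the photosynthesis list, among them LHCB2.2, LHCB3 and LHCB4.1. Its result is therefore not separate from that of the list. No stem passed against matched lists (lowest adjusted permutation p = 0.0724). That value is for LHCB, whose unadjusted permutation p = 0.0002 is the smallest 10000 lists can give. Over 362 stems a single stem could therefore not pass, whatever its binding.

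Binding at 17 of the 18 listed photosynthesis genes was weighed against 3 technical explanations. Another, signal that the antibody recovers without SOB3-GFP, could not be tested, because the series held no precipitation from plants without the fusion. Gene length and spacing are argued against by the matched lists (permutation p = 0.0002, the smallest 10000 lists can give), and reads shared between near-identical copies by the 9 members left without LHCB1, LHCB2 and RBCS, of which 8 were bound (Fisher's exact p = 2.44e-07). Signal at highly transcribed genes stays open, because transcription was not measured here: of 61 housekeeping and ribosomal protein genes 11.5% were bound in both replicates, against 11.5% of other genes (Fisher's exact p = 1), 31.1% against 28.7% in the replicate 1 list (p = 0.672) and 14.8% against 13.7% in the replicate 2 list (p = 0.851). Taken separately, the replicate 1 list held 9 of 12 housekeeping genes (adjusted exact p = 0.00462, and 0.0135 against matched lists) and 10 of 49 ribosomal protein genes (adjusted exact p = 0.314). For the place of the summit, only the region with the highest lower fold was taken per gene. Its summit lay inside the gene span in 12 of the 17 bound genes (70.6%). The share was 18.4% for all bound genes and 31.3% for the bound photosystem genes outside the list. No biological explanation was tested.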
